A study of Solanum lycopersicum with 2 samples.

How the data were processed

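Total RNA of red ripe tomato fruit was sequenced on the Illumina platform as 1 library of the wild type and 1 library of an ALMT9 overexpression line, per the labels. The labels give harvest at 49 days after flowering from 3 plants of each genotype. The authors deposited 1 table with an RPKM value per gene identifier and library, that is, read counts divided by gene model length and by the reads of the library. The submitters' processing notes name TopHat, a spliced read aligner, without a version. The counting tool, genome build, annotation release, strand setting and treatment of reads with several positions are not given in the sources used here. Counts of overlapping, antisense or near-identical genes are therefore uncertain. The table columns were assigned to samples by the endings of the sample titles, and groups by the genotype label.

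The table kept genes at 0 and showed no filter. RPKM was tested for traces of whole reads, because a value of whole reads is a multiple of what 1 read is worth. Ratios of the 2 columns were whole-number ratios times 1 common factor, 1.0252, which is the ratio of the library totals. Totals were then found as the largest for which lengths of most trial genes came out whole, which was 76.5% of them against 38.5% at 2 times and 41.4% at 3 times these totals. These were 19736832 reads (wild type) and 19252026 reads (overexpression), each within 0.00012 of a whole number. For 24427 of the 24429 genes above 0 (99.99%), a length of at least 60 bp was found at which both values were whole reads, within the rounding of the printed values. The shortest such length was taken, so read numbers are the smallest the values allow and can be whole fractions of the true ones. They sum to 17006911 and 16420926 reads, 86.2% and 85.3% of the totals. Median recovered length was 1055 bp. The recovery was tested on simulated data for this comparison. It returned both totals without error and, of 2895 genes, gave 84.6% of read numbers exactly and 99.6% exactly or as a whole fraction. The simulation took the recovered lengths as true, so the share of exact read numbers need not hold for the deposited values.

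Values were compared as log2((overexpression + 1)/(wild type + 1)), with a pseudocount of 1, among genes with a mean RPKM of at least 1. This scale understates ratios of low genes. With 1 library per genotype no test was run. Genes at least 2-fold higher or lower were counted by a fixed rule of size. In the simulation of 24427 genes, the rule found 100 of 100 genes raised 4-fold and 100 of 100 lowered 4-fold. These were drawn only from genes with at least 100 expected reads and at least 5 RPKM, where such changes pass easily. The simulation therefore does not show how many changes of weaker genes are missed. The rule also called 72 of 17075 unchanged genes. For single genes the RPKM ratio has an exact (Clopper-Pearson) 95% interval from the recovered reads. For list medians the interval comes from 2000 Poisson draws of the reads. PCR copies are not independent molecules, and all intervals cover counting error only. Too small read numbers make them too wide. For a list of loci, the median log2 ratio was placed among 10000 random lists of the same size, matched on mean expression in 20 bins. That percentile describes these libraries and is not a p-value. A list was called apart from random lists where its median lay outside their central 95%. In the simulation a list of genes raised 4-fold lay at percentile 100.0. A list of unchanged genes lay at percentile 4.2, so such a place can arise without a change.

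Lists, thresholds, random list settings and the rule for named genes were set before the data were examined. The rule named the ALMT loci, the 12 highest and 12 lowest ratios with a known description at a mean RPKM of at least 5, and members of the lists. None of the identifiers matched the 41476 genes of the reference table. The part of the rule that needs descriptions was therefore reduced to 2 identifiers in each direction. Another 20 lists defined by gene descriptions were not used here. These covered the ALMT family, malate and citrate metabolism, vacuolar proton pumps, markers of green tissue, seed, epidermis and dividing cells, and others. The 5 lists used hold 55 loci, all present in the table, entered from published tomato locus assignments known beforehand. These assignments could not be checked against a table, so list members are not named singly. The median level of the listed loci lay between percentiles 91.3 and 99.2 of all genes, depending on the list. Alternatives covered the pseudocount, the filter on low values, the threshold, 5 scalings and unmatched random lists. A correction for length and a minimum of 20 reads were added after seeing the data. Calculations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.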

Results

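RNA sequencing compared red ripe tomato fruit of the wild type with fruit of a line overexpressing ALMT9, a gene of the aluminum-activated malate transporter family. Members of this family are membrane channels that carry malate, one of the main organic acids of tomato fruit. The series asks which genes change with ALMT9 in ripening fruit. Fruit was taken 49 days after flowering from 3 plants of each genotype, and 1 library stands for each genotype. The labels do not say whether fruit of the plants was pooled. No difference below therefore has a replicate check, no p-value is given, and every comparison describes these 2 libraries rather than the genotypes. The table held RPKM values (read counts normalised by gene model length and library size) of 34725 tomato gene identifiers. Library totals recovered from the values were 19736832 reads for the wild type and 19252026 for the overexpression line. Of all identifiers, 11740 were listed at 0 in the wild type and 11421 in the overexpression library. The identifiers are not paired with gene names in the sources used here, so genes are given by identifier or as members of lists of loci fixed in advance.

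The overexpression library held far more reads of the locus entered for ALMT9. This locus, Solyc06g072910.2, numbered on chromosome 6 by its identifier, went from 0.0742 RPKM in the wild type to 20.5 RPKM in the overexpression library. The adjacent identifier, Solyc06g072920.1, entered in advance as the ALMT neighbour of this locus, went from 0.175 to 39.0 RPKM. The pairing of both identifiers with ALMT genes rests on knowledge of the study and of tomato loci, not on a table used here. The RPKM ratio was 277 for the first locus, from at least 1 read against at least 270 reads, with an exact 95% counting interval of 49.3 to 11000. For the second locus the ratio was 223, from at least 4 against at least 872 reads, with an interval of 87.0 to 822. On the log2(RPKM + 1) scale the differences were 4.33 and 5.09, ranks 12 and 4 among the 17287 genes with a mean RPKM of at least 1. The direction of both matched the label of the overexpression library. They may not be separate signals, since 1 transcript read across both gene models could not be told apart from separate changes. These intervals cover counting error only, and reads of near-identical family members, or of an introduced copy, could not be told from those of the resident genes.

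Across the transcriptome most genes stayed close between the 2 libraries, and genes higher in the overexpression library outnumbered lower ones. Of the 17287 genes with a mean RPKM of at least 1, 1398 (8.09%) were at least 2-fold higher on the log2(RPKM + 1) scale. Another 744 (4.3%) were at least 2-fold lower, and 87.6% lay within 2-fold. At 4-fold, 341 genes were higher and 94 were lower. The median log2 ratio was 0.016, with an SD of 0.74 across genes. Across all genes, log2 values of the libraries had a Pearson r of 0.973 and ranks had a Spearman rho of 0.961. Genes are not independent replicates. If both libraries had equal rates for every gene, counting error alone gave a mean of 69.1 genes at 2-fold over 100 simulated pairs, and 88 at most.

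The excess of higher genes was larger among weakly expressed genes. Split into 4 classes of equal size by mean RPKM, the lowest class of 4322 genes held 518 genes at least 2-fold higher and 185 lower. The highest class, also of 4322 genes, held 272 and 198. A total of 73 genes were listed at 0 in the wild type and at 1 RPKM or more in the overexpression library, against 35 in the opposite direction. Such levels can rest on few reads in short gene models, as at Solyc00g168200.1, with 1.51 RPKM from 2 recovered reads. How many such genes counting error alone would give was not worked out. Among genes with a mean RPKM of at least 5, the highest differences on the log2(RPKM + 1) scale belonged to Solyc06g034370.1, with 0.613 RPKM in the wild type and 98.9 RPKM in the overexpression library, and Solyc08g079870.1, with 1.29 and 133 RPKM. Their values on this scale were 5.95 and 5.87. The lowest on the same scale belonged to Solyc08g080490.2, with 93.0 RPKM in the wild type and 0.82 RPKM in the overexpression library, and Solyc09g025210.2, with 57.1 and 0.613 RPKM. Their values on it were -5.69 and -5.17. Exact 95% counting intervals of the RPKM ratio were 78.1 to 402 and 65.7 to 171 for the higher pair. For the lower pair they were 0.00439 to 0.0158 and 0.00655 to 0.0166.

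**Figure D1:**
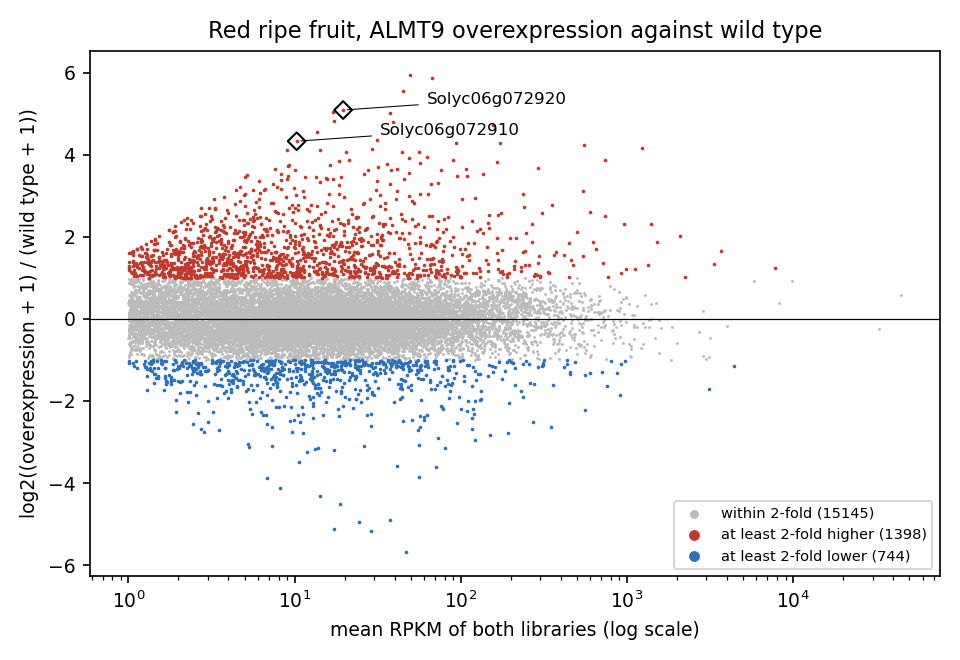
Each point is 1 of the 17287 genes with a mean RPKM of at least 1, placed by its mean RPKM over both libraries (log axis) and by its log2((overexpression + 1)/(wild type + 1)). The 1398 genes at least 2-fold higher are red and the 744 at least 2-fold lower are blue. Open diamonds mark the locus entered for ALMT9 at 4.33 and the adjacent locus at 5.09.

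Loci entered for ethylene synthesis and perception stood higher in the overexpression library as a list, although the receptor loci within it did not. Ethylene is the hormone that drives ripening of tomato fruit. Of the 15 loci, 10 were above 0 on the log2 scale, 5 of them by at least 2-fold, and 5 were below 0, none of them by 2-fold. The median log2 ratio was 0.48, a 1.4-fold difference, with a counting interval of 0.36 to 0.56. It lay at percentile 98.9 of 10000 random lists matched on expression, 95% of which lay between -0.3 and 0.41. With a mean RPKM of at least 5 required, 13 loci remained and their median of 0.32 lay at percentile 94.6, inside the central 95% of random lists. With a pseudocount of 5 the median was 0.3, at percentile 95.7 and also inside.

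The list holds loci entered for enzymes that form ethylene, for receptors that sense it, and for neither. These parts are described apart here by a split made after the values were seen, and the difference between them was not tested. All 7 loci entered for ACC synthases and ACC oxidases, the enzymes of the last steps of ethylene synthesis, were higher in the overexpression library. Their median log2 ratio was 1.11. The most abundant of them went from 648 to 2360 RPKM, a ratio of 3.65 with a counting interval of 3.59 to 3.71. The next went from 305 to 993 RPKM, a ratio of 3.25 with an interval of 3.18 to 3.32. The 4 loci entered for ethylene receptors had a median of -0.19. Receptors at 233 and 26.4 RPKM in the wild type were at 144 and 17.0 RPKM in the overexpression library, and those at 231 and 18.9 RPKM were at 271 and 23.8 RPKM. Among the loci that are neither such enzymes nor receptors, 3 were lower in the overexpression library. They were at 3980 and 2010, 1700 and 1230, and 58.9 and 52.3 RPKM in the wild type and the overexpression library. The first of these was the most abundant locus of the whole list in the wild type. The remaining 1 was higher, at 76.0 and 117 RPKM.

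Loci entered for flavour volatiles stood lower as a list. They were entered for enzymes placed in the formation of fatty acid, amino acid and alcohol volatiles of ripe fruit. The part each member plays in these volatiles was not checked here. Of the 7 loci, 5 were below 0 on the log2 scale, 2 of them by at least 2-fold, and 2 were at least 2-fold higher. The median log2 ratio was -0.62, a ratio of 0.65, with a counting interval of -0.63 to -0.6. This median is the value of 1 of the 7 loci, so its narrow interval is the counting error of that locus. The median lay at percentile 0.6 of random lists, whose central 95% ran from -0.44 to 0.55. The most abundant member went from 6040 to 2730 RPKM and the third most abundant from 1240 to 498 RPKM. The member with the highest ratio went from 3.45 to 25.3 RPKM, and the mean log2 ratio of the list, -0.09, was closer to 0 than the median. With a length trend between the libraries taken out, a step added after seeing the data, the median was -0.45, at percentile 3.0 and inside the central 95%.

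Loci of the carotenoid pathway, which makes the red pigment lycopene and its products, had a median below 0 but did not stand apart from random lists. Of the 16 loci entered, 15 had a mean RPKM of at least 1, 10 of them below 0 and 5 above. The median log2 ratio was -0.25, with a counting interval of -0.34 to -0.14, at percentile 5.0. Central random lists ran from -0.31 to 0.35. Single members differed by more than counting error, with 9 intervals of the RPKM ratio below 1, 3 above 1 and 3 spanning it. The most abundant member went from 2410 to 1610 RPKM. The only member at least 2-fold lower went from 133 to 52.6 RPKM, and the only member at least 2-fold higher went from 135 to 326 RPKM.

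Loci entered for ripening regulators and for fruit softening did not stand apart as lists. The 7 regulators, transcription factors that control ripening, had a median log2 ratio of -0.11, at percentile 24.7. Of these, 6 lay within 2-fold, and 1 went from 224 to 98.1 RPKM. The 10 softening loci, for proteins that loosen or degrade the cell wall, had a median of -0.14, at percentile 16.5, with 5 above and 5 below 0. The 2 most abundant in the overexpression library, at 3070 and 1700 RPKM, had 2680 and 1300 RPKM in the wild type. In contrast, 1 member went from 1300 to 638 RPKM and another from 77.2 to 22.6 RPKM. With a mean RPKM of at least 5 required, 1 member of 2.14 and 7.21 RPKM dropped out and the median of the other 9 was -0.48, at percentile 1.2 and outside the central range.

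**Figure D2:**
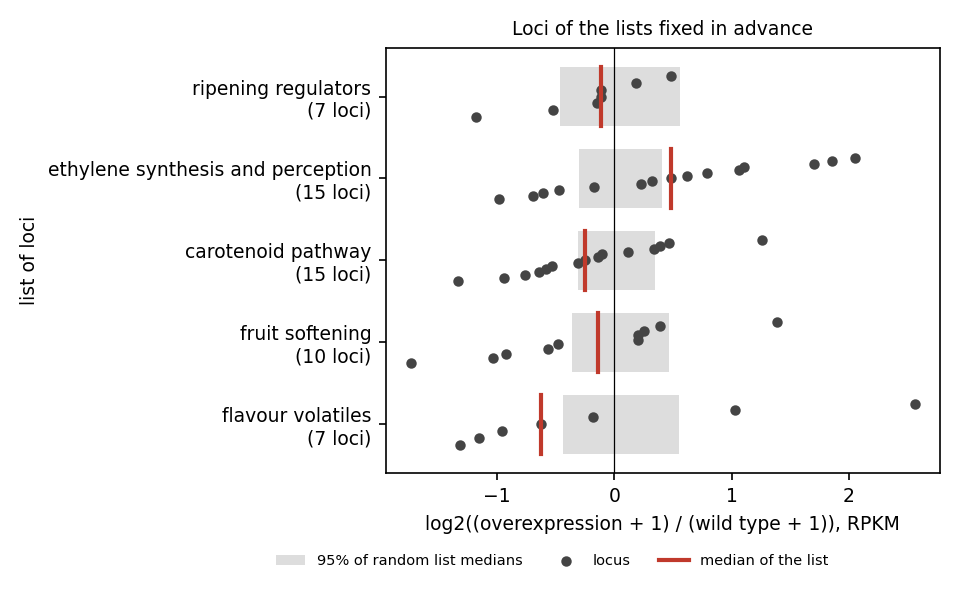
Each dot is the log2((overexpression + 1)/(wild type + 1)) of 1 locus of a list fixed before the data were examined, with the list median as a red line and the central 95% of medians of 10000 random lists as a grey band. The ethylene median of 0.48 lies above its band and the flavour median of -0.62 below, whereas the other 3 medians lie inside theirs.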

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

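Direction held in each alternative run for the counts of genes, the list medians and the ALMT9 level, and no list median reversed. The number of genes at least 2-fold apart (2142, with 1398 higher and 744 lower) was 1009 (667 and 342) with a pseudocount of 5. It was 1414 (860 higher) with a mean RPKM of at least 5 and 1050 (621 and 429) with at least 10. It was 4982 (2819 and 2163) at 1.5-fold and 435 (341 and 94) at 4-fold. Each remaining setting, all scalings included, stayed within 1.5 times. The ALMT9 difference of 4.33 was 6.89, 5.2 and 2.33 with pseudocounts of 0.1, 0.5 and 5, against a wild type level of 0.0742 RPKM. Scaling to equal sums used a factor of -0.089 on the log2 scale for the overexpression values, and low genes move by less than that. With it the list medians were -0.2 (regulators), -0.23 (softening) and -0.71 (flavour). Without the 100 highest genes in the sum they were -0.17, -0.2 and -0.67. The trimmed mean gave -0.66 for flavour, and taking out the length trend, an alternative added after seeing the data, gave -0.45 at percentile 3.0, inside the central 95% of random lists. The ethylene median of 0.48 was 0.3 with a pseudocount of 5 and 0.32 with a mean RPKM of at least 5 or 10, its percentile moving from 98.9 to 95.7, 94.6 and 94.3. The softening median of -0.14 was -0.48 at both filters, since 1 low locus left the list. The carotenoid median stayed within its counting interval in all 13 alternatives. Pearson r across genes of 0.973 was 0.926 for genes with a mean RPKM of at least 1. The 108 genes listed at 0 in one library (73 in the wild type and 35 in the overexpression library) depended on the level required in the other. They were 293 (173 and 120) with 0.5 RPKM required and 30 (24 and 6) with 2 RPKM. No paired analysis was possible because each genotype has 1 library, and no replicate could be left out for the same reason. Depth leaves the ALMT9 ratio imprecise, since the wild type may hold as little as 1 read of it (counting interval of the ratio 49.3 to 11000).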

Other observations

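Changed genes were spread over the whole genome, as far as the chromosome numbers in the identifiers show. On the 12 numbered chromosomes, between 133 of 1208 genes (chromosome 11) and 168 of 1222 genes (chromosome 9) were at least 2-fold apart, and higher genes outnumbered lower ones on all 12. Log2 ratios of neighbouring expressed loci were only weakly correlated, with a Pearson r across genes of 0.125 for direct neighbours, against at most 0.021 over 100 shuffles of the loci. At 10 loci apart r was 0.014, below the highest shuffled value of 0.019. Genes are not independent replicates, and tandem copies that share reads were not separated.

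Among the tests below, those of a single transcript over both ALMT loci and of the chance order of loci were chosen after the results they measure were seen. The length correction and the run on chromosome 1 were also chosen after seeing the data, although the bounds for the length tests were written before their outcome was known. The bounds for the loci flanking the ALMT pair, for counting noise and for scaling were written before as well.

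A run of neighbouring loci numbered on chromosome 1 was lower in the overexpression library. It was picked as the window of 25 expressed genes with the lowest median log2 ratio on any numbered chromosome, so its values are a selected extreme. From Solyc01g007260.2 to Solyc01g007540.2 the median log2 ratio of the 25 genes was -0.85. Median levels were 9.1 RPKM in the wild type and 5.7 RPKM in the overexpression library. Of the 25 genes, 24 lay below 0 and 9 were at least 2-fold lower. The fixed window size sets the ends of the run, which are not bounds of the lower region. The next expressed loci, Solyc01g007550.1 and Solyc01g007560.2, had log2 ratios of -0.77 and -0.82. The tables argue against the chance order of loci, since 0 of 100 shuffles held a window of 25 as low and the lowest reached -0.54. They also argue against a length trend, since the medians of 10 length classes over all genes lay only between -0.12 and 0.07. With the trend taken out the median of the window was -0.93. A correction that small could hardly have moved it far, so this value adds little. A shared origin of the reads, such as copies of these sequences elsewhere in the cell, and a real change of the region stay open, and neither was tested.

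The pair of ALMT loci was raised as a pair. A wider stretch raised like the pair is argued against, since the 5 loci before and the 5 after it had a median log2 ratio of -0.14 and lay between -0.43 and 0.45. The 2 of these with a mean RPKM of at least 1 went from 17.0 to 14.0 and from 6.96 to 6.24 RPKM. The others stayed below 0.5 RPKM in the overexpression library, so a small rise from such low levels stays open for them. The hypothesis that 1 raised transcript may have been read across both gene models cannot be told apart from separate changes. The RPKM ratio of the first locus was 1.24 times that of the second with overlapping counting intervals, but the wild type held as few as 1 and 4 reads. An introduced copy and the resident genes were not separable in these values.

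Genes at least 2-fold higher outnumbered lower ones by 1.88 to 1. Counting noise is argued against as the source of most 2-fold genes, because simulated libraries of equal rates gave 3.2% as many. Their ratio of higher to lower genes, 1.01, was set by the equal rates and is no evidence. The simulated libraries held counting error only, without differences between fruits or library preparations. A length trend exists, with a median log2 ratio of -0.12 in the longest of 10 length classes (recovered length of at least 2493 bp) and 0.07 in the second shortest. Without it the ratio was still 1.73, which argues against the trend as the whole cause. Taking it out also centres the log2 ratios, and centring alone gave 1.76, so little of the fall goes with length. Recovered lengths can be whole fractions of the true ones, which limits this correction. Over 5 scalings the lowest ratio was 1.42, between the bounds set for and against scaling as the cause, so a part played by scaling stays open. The genotype, the fruit sampled and the library itself cannot be told apart with 1 library each.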
